A study of Homo sapiens with 11 samples.

How the data were processed

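Total RNA of 11 cultures of 2 human cell lines, RPE-1 and BJ, was measured on 1 array per sample: BJ diploid (n = 2), BJ tetraploid (n = 3), RPE diploid (n = 3) and RPE tetraploid (n = 3). The stated design is of biological samples in triplicate, and the BJ diploid group has 2 arrays in the sources used here. The title of BJ tetraploid array 1 carries the extra word Late; the array was kept in its group. The deposited values are log2 probe set expression after RMA (background correction, quantile normalization and median polish), per the submitters' processing notes, which name RMA and the R package affy without a version. The genome build, the probe annotation and the date of each scan are not given in the sources used here. No array was left out, and the number of arrays limits the precision.

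Of the probe sets on the array, 62 controls were set aside, 41091 had exactly 1 gene symbol, 1801 had several and 11721 had none. Each of 19777 genes was represented by its probe set with the highest mean over all 11 arrays (10523 genes had more than 1), with no filter on dim genes. A reference gene table placed 19687 genes on chromosomes 1 to 22 or X. RNA quality was read as the log2 difference between the 3' and 5' control probe sets for actin and for GAPDH, and compared between groups by a two-sided exact permutation test, whose smallest possible p is 0.1 for 3 arrays against 3 and for 2 against 3.

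A linear model with 4 groups was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (7 residual degrees of freedom, moderated variances with default settings), so that the BJ diploid group, with 2 arrays, borrowed the spread of the others. The contrasts were tetraploid minus diploid in RPE, the same in BJ, the RPE change minus the BJ change, and RPE diploid minus BJ diploid. The p-values were adjusted by Benjamini-Hochberg over all genes, and genes at an adjusted p under 0.05 were called. Errors of changes are standard errors from the model, and errors of group means are SD. Genes called in the same direction in both lines were compared with the number from independent lists by Fisher's exact test, and the changes were correlated across genes.

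The 28 gene lists covered signalling, cell cycle, cytoskeleton and matrix, stress and metabolism, and cell type markers. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way. Chromosomes were tested in the same way. Groups, contrasts, lists, thresholds and the rule for naming genes were chosen before the data were examined. That rule named, for each tetraploid comparison, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups (by chance 10% of genes show no overlap for 3 arrays against 3, and 20% for 2 against 3), and 10 fixed genes, 9 of which had a value. It also named up to 2 called members per direction in each list, 8 shared genes per direction, and 5 genes per direction for the difference between lines and for the diploid cells. Genes with placeholder symbols were passed over. CCND1, CDKN1A and CCN1 were tested for a difference between the lines after their changes were seen.

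The model was tested on simulated data, 5 times for each line, with 200 of 19777 genes changed. In RPE it recovered 70.5% of genes changed by 0.5 and 97.8% of those changed by 1 on the log2 scale, with 5.37% false calls. In BJ it recovered 63.2% and 97.8%, with 3.58% false calls. A list shifted by -0.3 was called in 5 of 5 simulations in each line, and 1 of 135 other lists was called. The simulated genes varied independently of each other, so this does not give the rate of false list calls in real arrays.

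Alternatives chosen in advance changed the probe sets used (every probe set, the mean of a gene's probe sets, or no probe sets with the suffix _x_at or _s_at, which can match related transcripts), the normalization between arrays (quantile, median centring, cyclic loess), a filter on genes under the 40th percentile of brightness, and a minimum absolute log2 change of 1. Others changed the variance model, array weights, the arrays in the model, a replicate block, the list test, or left out each array in turn. After the data were seen, 4 alternatives were added: the actin 3' to 5' difference as a covariate, both RPE arrays numbered 1 left out, genes of chromosome 12 left out, and windows of 40 neighbouring genes, whose level came from 1000 permutations of gene order. The windows held only genes past the 40th percentile of brightness. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.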

Results

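Gene expression was measured in diploid and tetraploid cells of 2 human lines on 11 oligonucleotide arrays. Each array was hybridised with labelled cRNA made from total RNA. RPE-1 (RPE) is a line of telomerase-immortalised retinal pigment epithelial cells, and BJ is a line of foreskin fibroblasts. Diploid BJ cells had 2 arrays, and tetraploid BJ, diploid RPE and tetraploid RPE cells had 3 arrays each. The tetraploid cells are described as evolved. How they were made, and how long they were grown, is not given in the sources used here. Array medians lay between 5.98 and 6.04 on the log2 scale. Across probe sets, arrays of the same group correlated at 0.9932 to 0.9966, arrays of the same line and the other ploidy at 0.9899 to 0.9942, and arrays of different lines at 0.9623 to 0.9673.

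The first comparison asked which genes changed in tetraploid RPE cells. Among the largest rises were those of CXCL8, the neutrophil chemokine interleukin 8 (log2 change 2.21 ± 0.274 SE, 4.64-fold, n = 3 against 3, adjusted p = 0.000229), PTX3, a secreted pattern recognition protein (1.76 ± 0.173), PLAT, tissue plasminogen activator (1.74 ± 0.0958), and SPP1, the secreted glycoprotein osteopontin (1.72 ± 0.107). HOXB6 (1.96), the small GTPase gene GEM (1.61), the membrane-bound metalloproteinase gene MMP16 (1.52) and TMEM200A (1.52) also rose. The largest falls were of the mitochondrial protein gene MGARP (-2.64 ± 0.159), GFRA1, a receptor for glial cell line-derived neurotrophic factor (-2.09 ± 0.0917), and IGFBP5, which binds insulin-like growth factors (-1.89 ± 0.0928). TSPAN2 (-1.85), NXN (-1.74), KCTD20 (-1.68), the neurexin gene NRXN3 (-1.67) and the heparan sulfatase gene SULF1 (-1.62) fell as well. In these 16 genes, which were chosen among those whose groups did not overlap, adjusted p was at most 0.000664. In HOXB6, SPP1, MGARP and TSPAN2 the lower group lay under the median of every array, where signal over background is unknown, so the sizes of these changes are uncertain. Of 19777 genes, 1092 passed the threshold, 426 higher and 666 lower, and 79 of them changed at least 2-fold. Without RPE diploid array 1 the numbers were 358 higher and 409 lower. The count fell to 688 (280 higher and 408 lower) without RPE tetraploid array 2 and to 590 without both RPE arrays numbered 1, whose actin 3' to 5' differences of 0.46 and 0.556 were the highest among the RPE arrays. The HOXB6 call rested on a probe set that can match related transcripts, and without probe sets of that kind its change was 0.000854. With the mean of each gene's probe sets the changes were smaller for HOXB6 (0.983), SPP1 (0.915), MMP16 (0.687), IGFBP5 (-0.809), TSPAN2 (-1.01) and NRXN3 (-0.755), all still past the threshold.

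Among genes fixed in advance, CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose in tetraploid RPE cells (0.53 ± 0.0784, adjusted p = 0.00103), and CCN1, a matricellular protein gene and a target of the transcriptional coactivator YAP, fell (-0.57 ± 0.0953, adjusted p = 0.00249). CCN2, another such target, fell by 0.47 (adjusted p = 0.042). Its call was lost without any 1 of BJ tetraploid arrays 1, 2 and 3, RPE diploid arrays 1 and 2 and RPE tetraploid arrays 2 and 3, with changes of -0.534 to -0.336 and adjusted p up to 0.174. CCND1, which encodes cyclin D1, differed by 0.26 (adjusted p = 0.0612), LATS2, a Hippo pathway kinase gene, by -0.34 (adjusted p = 0.0551), MDM2, the p53 ubiquitin ligase gene, by 0.43 (adjusted p = 0.495), and CCND2 by 0.24 (adjusted p = 0.378), and none of them passed. The differences of YAP1 (0.01, adjusted p = 0.977) and of its target ANKRD1 (-0.06, adjusted p = 0.919) did not pass either. Another of the 4 probe sets of LATS2 passed, with a change of -0.356 (adjusted p = 0.0252 over all probe sets).

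The list of contractile actin cytoskeleton genes had a negative median in tetraploid RPE cells. Of its 24 measured members, 12 fell and 0 rose (14 fell when adjusted over the list alone). Among them were ACTA2, smooth muscle actin (-1.07 ± 0.149), and MYL9, a myosin regulatory light chain (-1.06 ± 0.0829; -0.634 with the mean of its probe sets, and -0.208 and adjusted p = 0.148 without probe sets that can match related transcripts). The median change was -0.344 (adjusted p = 2.85e-14 by camera, and adjusted p = 0.0861 with an estimated correlation), and -0.173 with the mean of each gene's probe sets, which gave -0.409 for ACTA2. Of 21 measured members of a 22-gene signature of targets of YAP and its TEAD partners, 11 fell and 0 rose (17 fell when adjusted over the list alone). TGFB2, a transforming growth factor (-1.13 ± 0.0882), and RBMS3 (-0.96 ± 0.167) were furthest down. The median was -0.338 (adjusted p = 5.46e-12, and adjusted p = 0.234 with an estimated correlation). Of 9 smooth muscle markers, 3 fell, with LMOD1 at -1.53 ± 0.144. The median was -0.15 (adjusted p = 0.000899, and adjusted p = 0.234 with an estimated correlation). It ran from -0.36 without dim genes to -0.0652 without RPE diploid array 2, and was -0.226 without RPE diploid array 3 and -0.0767 with the mean of each gene's probe sets. This list shares 3 members with the actin list, and adjusted over the list alone the count was also 3. Of 29 extracellular matrix genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone). The collagen genes COL1A1 (-1.50 ± 0.239) and COL4A1 (-1.30 ± 0.116) fell, and LOX, which crosslinks collagen, rose (0.44 ± 0.0649). The median of the matrix list was -0.129 (adjusted p = 3.16e-06, and adjusted p = 0.276 with an estimated correlation). It was -0.241 without genes of chromosome 12, -0.207 without RPE diploid array 3 and -0.237 without RPE tetraploid array 3. With the mean of each gene's probe sets the median of YAP and TEAD targets was -0.225, and the changes of RBMS3 and COL1A1 were -0.597 and -0.592.

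More Hippo pathway components fell than rose in RPE cells. Of 26, 6 fell and 1 rose (7 and 2 adjusted over the list alone). The rise, of VGLL4, lost its call without RPE diploid array 2 or 3 or RPE tetraploid array 1 or 3. VGLL3, a TEAD cofactor gene (-1.45 ± 0.146), and WWC1 (-0.83 ± 0.126; -0.357 with the mean of its probe sets, -0.0774 without probe sets that can match related transcripts) fell. The median was -0.0672 (adjusted p = 0.0071; 0.0713 without RPE diploid array 1, and adjusted p = 0.467 with an estimated correlation). It was -0.0384 (0.07) with the mean of each gene's probe sets, -0.119, -0.111 and -0.115 without RPE diploid array 2, RPE tetraploid array 1 and RPE tetraploid array 3, and adjusted p was 0.08 by fry. Of 33 growth factors and receptors, 5 fell and 1 rose (8 and 1 adjusted over the list alone). TGFB2 and the platelet-derived growth factor receptor gene PDGFRB (-0.81 ± 0.112) were among those that fell, and KITLG rose (0.32 ± 0.0661). The median was -0.0723 (adjusted p = 0.0232; 0.0596 without RPE tetraploid array 1, 0.0948 without dim genes, and adjusted p = 0.237 with an estimated correlation). The median was -0.0321 without RPE tetraploid array 1 and -0.042 without RPE diploid array 2. It was -0.011 (0.288) with the mean of each gene's probe sets, which also ended the KITLG call (0.185, adjusted p = 0.205). Of 14 cholesterol synthesis genes, 2 fell (2 adjusted over the list alone). These, SC5D and STARD4, both lost their calls without RPE diploid array 1 or RPE tetraploid array 2 or 3. The median was -0.128 (adjusted p = 0.00738; 0.0513 without RPE tetraploid array 3, 0.0589 by fry, and adjusted p = 0.298 with an estimated correlation).

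Lists that shifted upwards in RPE cells held p53 targets, mitosis genes, inflammatory factors and stress response genes. Of 27 p53 targets, 5 rose and 1 fell (8 and 1 adjusted over the list alone). CDKN1A and the death receptor gene TNFRSF10B (0.40 ± 0.0756; 0.242 and adjusted p = 0.327 with the mean of its probe sets) led the rises. The median was 0.159 (adjusted p = 0.000122, and adjusted p = 0.237 with an estimated correlation). Of 30 mitosis genes, 4 rose and 0 fell (4 adjusted over the list alone). The median was 0.133 (adjusted p = 6.34e-06, and adjusted p = 0.237 with an estimated correlation). FOXM1, a transcription factor of the mitotic programme (0.65 ± 0.0641), and RACGAP1 (0.46 ± 0.0754) are both on chromosome 12. Of 22 secreted inflammatory factors and proteases, 6 rose and 2 fell (6 and 2 adjusted over the list alone). CXCL8 and IL1B, interleukin 1 beta (0.98 ± 0.171), rose and CCL2, a monocyte chemokine (-1.18 ± 0.219), fell. The median was 0.119 (adjusted p = 0.00334, 0.0584 by fry, and adjusted p = 0.298 with an estimated correlation), 0.29 without dim genes and 0.0792 with the mean of each gene's probe sets. Of 21 genes of the endoplasmic reticulum stress and amino acid response, 5 rose and 1 fell (5 and 1 adjusted over the list alone). Its rises were led by the cystine transporter gene SLC7A11 (0.97 ± 0.133) and SHMT2 (0.59 ± 0.0708), an enzyme of one-carbon metabolism, and 3 of the 5 are on chromosome 12. The median of that list was 0.0732 (adjusted p = 0.0132, and adjusted p = 0.467 with an estimated correlation), and the call was lost by fry (0.111), without the genes of chromosome 12 (0.0356, adjusted p = 0.202) and without RPE tetraploid array 2 (0.0266, adjusted p = 0.116).

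The other 17 lists did not pass in RPE cells, with adjusted p from 0.113 to 0.827. Of 20 G1 cyclins, kinases and inhibitors, 2 rose, CDKN1A and CDK4 (0.53 ± 0.0775), the latter on chromosome 12 (5 adjusted over the list alone). Of 17 lysosome and autophagy genes, 2 rose, the cathepsin genes CTSL (0.72 ± 0.078) and CTSK (0.45 ± 0.0768), and 1 fell, CTSD (-0.44 ± 0.0727). Of 26 DNA replication genes 2 fell, and of 23 interferon-stimulated genes 1 fell. Of 15 epithelial markers 2 fell, the desmoplakin gene DSP (-0.82 ± 0.133) and the keratin gene KRT18 (-0.48 ± 0.0772), and of 16 retinal pigment epithelium markers 1 rose and 1 fell. Of 24 oxidative phosphorylation genes 2 rose, both on chromosome 12. Of 20 hypoxia and glycolysis genes 1 rose and 2 fell. In addition, 1 of 19 centriole and centrosome genes and 1 of 21 ribosomal protein genes rose, and 0 of 10 distal HOX genes, 0 of 10 histone genes and 0 of 10 leukocyte markers passed. Of 18 fibroblast markers 2 rose and 3 fell, and that list's median (0.0149) and mean (-0.0928) differed in sign.

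**Figure D1:**
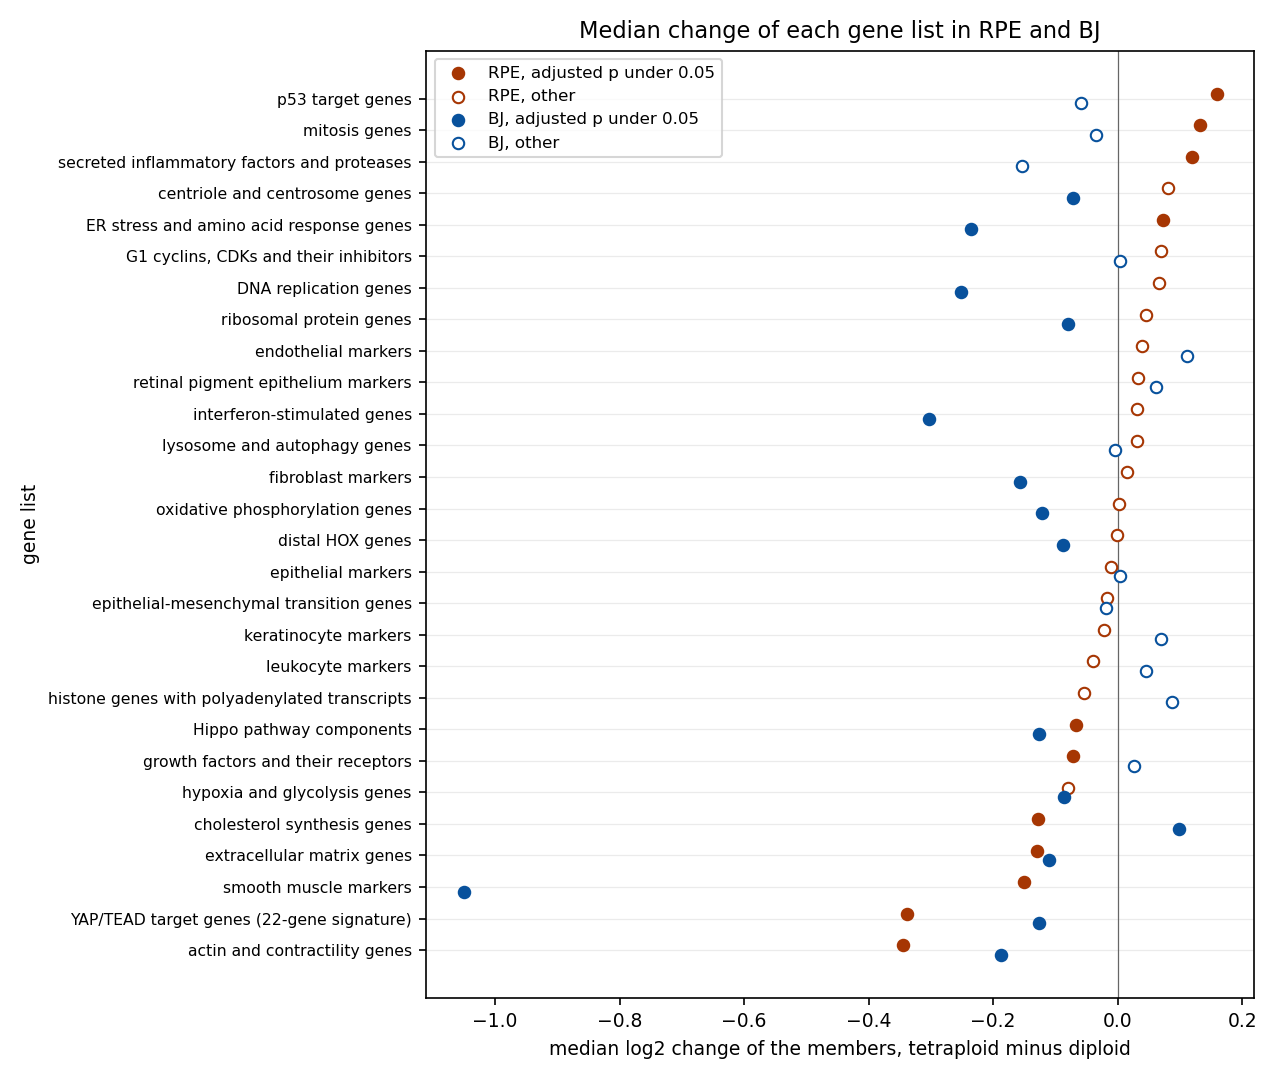
Median log2 change (tetraploid minus diploid, horizontal axis) of the measured members of each of 28 gene lists, in RPE (brown) and BJ (blue). Filled points had an adjusted p under 0.05 by camera with the preset correlation. The actin list had medians of -0.344 in RPE and -0.188 in BJ, and the smooth muscle list -0.15 and -1.05.

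Genes on chromosome 12 were higher in tetraploid than in diploid RPE cells along nearly the whole chromosome. Of the 426 genes called higher, 180 are on chromosome 12, or 42.3% against 5.23% of all genes. The odds ratio was 15.8 (Fisher's exact test p = 2.4e-118, and genes are not independent). The median change of its 1035 genes exceeded that of other genes by 0.0994 (adjusted p = 1.97e-16 by camera, and adjusted p = 0.000253 with an estimated correlation). Among its 651 genes in the brighter part of the range, the median in single tetraploid arrays, relative to the mean of the diploid arrays and to other genes, was 0.199, 0.187 and 0.184. The brighter genes were divided into windows of 40 neighbours, a division chosen after the chromosome medians were seen. Of 16 windows on chromosome 12, 15 were past 0.104, the level that shuffled gene orders set. Genes on chromosome 1 were lower: 160 of the 666 genes called lower are there (24% against 9.74% of genes; odds ratio 3.11), and 10 of its 29 windows were past the level downwards. The chromosome 1 median lay 0.0535 below that of other genes (adjusted p = 7.97e-05, and adjusted p = 0.00242 with an estimated correlation), with -0.0956, -0.0948 and -0.0934 in the brighter genes of the 3 tetraploid arrays on the same relative scale. No other chromosome passed in RPE cells.

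**Figure D2:**
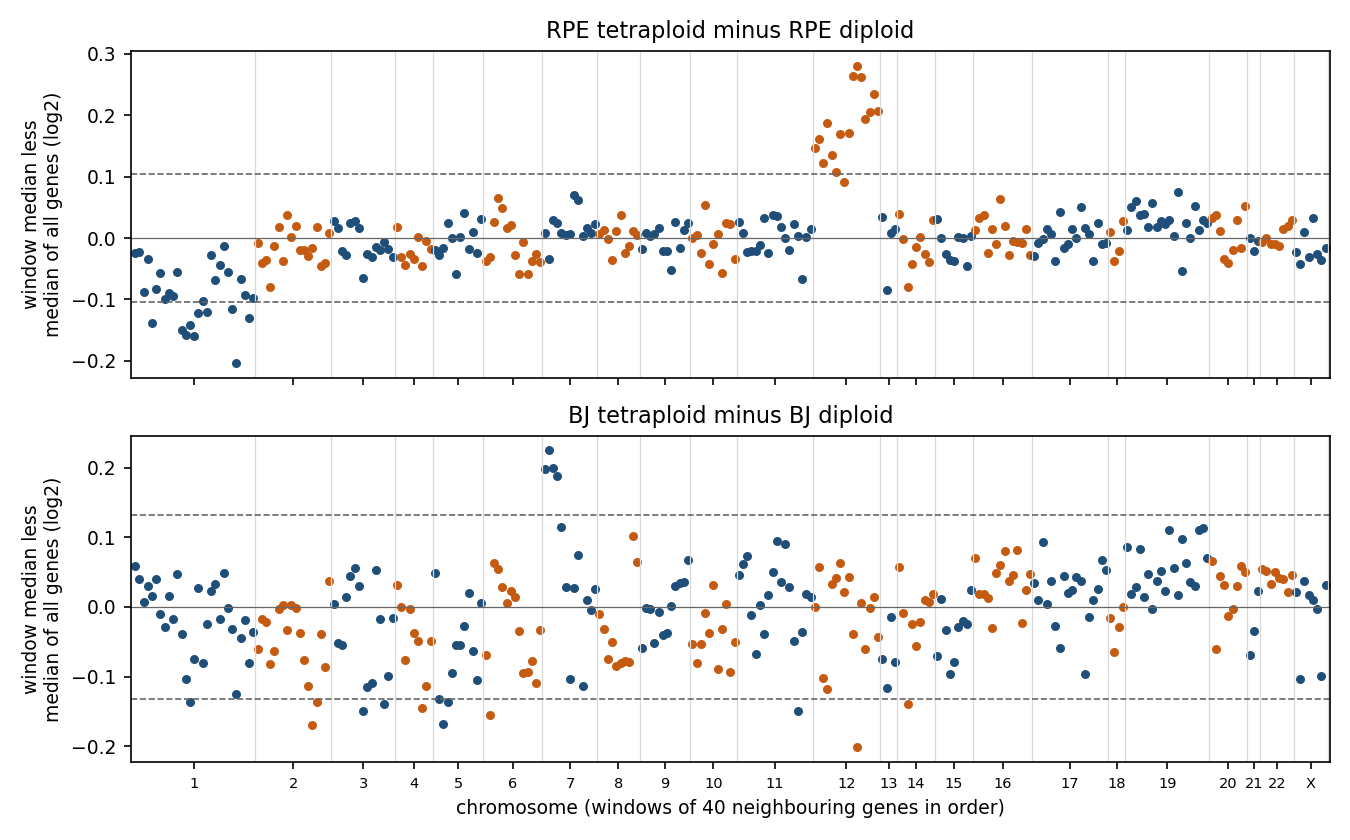
Median log2 change of windows of 40 neighbouring genes, less the median of all genes (vertical axis), in order along chromosomes 1 to 22 and X (horizontal axis) for RPE (top) and BJ (bottom). The windows held genes of the brighter part of the range only. Dashed lines mark 0.104 in RPE and 0.132 in BJ, the levels set by shuffled gene orders; 15 of 16 windows of chromosome 12 in RPE and the first 4 of 13 windows of chromosome 7 in BJ lie above them, and 13 windows on 9 chromosomes in BJ lie below.

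The second comparison asked which genes changed in tetraploid BJ fibroblasts. EDIL3, an integrin-binding matrix protein, rose by its brightest probe set (log2 change 3.88 ± 0.14 SE, n = 2 diploid and 3 tetraploid, adjusted p = 2.69e-09). PITX1, a homeobox transcription factor of the hindlimb (1.71 ± 0.125), the homeobox gene MKX (1.58 ± 0.157), STMN2 (1.57 ± 0.139), the translation factor gene EIF5A (1.30), SERPINB7 (1.25), the cyclooxygenase gene PTGS2 (1.25) and the keratin gene KRT19 (1.23) also rose. The largest falls were of TCIM (-2.54 ± 0.212), BEX1 (-2.33 ± 0.113), the Notch ligand gene JAG1 (-2.21 ± 0.14), the secreted WNT antagonist gene SFRP1 (-2.19 ± 0.0742) and the interferon-induced gene IFI27 (-2.16 ± 0.148). WFDC1 (-1.95), DIO2, which encodes a thyroid hormone deiodinase (-1.93), and the proteoglycan gene SRGN (-1.92) fell as well. In these 16 genes, which were chosen among those whose groups did not overlap, adjusted p was at most 0.00179. In EDIL3, PITX1, TCIM and IFI27 the lower group lay under the median of every array, so the sizes of their changes are read against values not shown to be above background. For EDIL3 these were 5.294 and 4.797 in the diploid arrays, and no fold is given. The EDIL3 rise was read from 1 of its 3 probe sets, and the others, at 1.04 (adjusted p = 0.12 over all probe sets) and 0.17 (0.852), did not pass. PITX1 had a change of 0.574 without probe sets that can match related transcripts. With the mean of each gene's probe sets the changes were smaller for EDIL3 (1.69), MKX (1.05), KRT19 (0.727), JAG1 (-1.08), SFRP1 (-1.36), DIO2 (-1.20) and SRGN (-1.11), all still past the threshold. Of 19777 genes, 788 passed, 176 higher and 612 lower, and 73 changed at least 2-fold. The count was 344 without BJ diploid array 1, 340 without BJ tetraploid array 1, 400 without array 2 and 499 without array 3, so that single arrays moved it by more than 1.5 times. Without BJ diploid array 2 it was 1069, 306 higher and 763 lower.

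RNA quality measures of the diploid and tetraploid BJ arrays did not overlap. The log2 difference between the 3' and 5' control probe sets of actin, which is larger where RNA is more degraded, was 0.443 ± 0.0539 (SD, n = 2) in diploid and 0.225 ± 0.0268 (SD, n = 3) in tetraploid arrays (exact permutation p = 0.1, two-sided, the smallest these arrays allow). For GAPDH it was 0.372 and 0.189. In RPE cells the actin difference was 0.285 ± 0.161 and 0.315 ± 0.212 (SD, n = 3 each; exact permutation p = 0.8). With the actin difference as a covariate, chosen after it was seen to differ, 310 genes passed in BJ, 83 higher and 227 lower. Because the BJ groups did not overlap, the covariate's slope came mostly from the spread among RPE arrays. It could not separate RNA quality from ploidy in BJ.

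CCND1 rose in tetraploid BJ cells (0.82 ± 0.0838, adjusted p = 7.6e-05), and no other gene of those fixed in advance passed. MDM2 differed by 1.02 (adjusted p = 0.0834), with BJ diploid arrays at 7.175 and 8.819 and 7 of its 10 probe sets moving the same way. CDKN1A differed by 0.22 (adjusted p = 0.203), LATS2 by -0.36 (adjusted p = 0.0787), CCND2 by 0.16 (adjusted p = 0.592), CCN2 by 0.15 (adjusted p = 0.606), CCN1 by -0.10 (adjusted p = 0.653), YAP1 by -0.05 (adjusted p = 0.857) and ANKRD1 by -0.33 (adjusted p = 0.392). The same other probe set of LATS2 passed in BJ too (-0.409, adjusted p = 0.0337 over all probe sets), and 2 of its 4 probe sets were lower.

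The lists of smooth muscle markers and of actin genes had negative medians in tetraploid BJ cells, and the latter did not pass with an estimated correlation. Of 9 smooth muscle markers, 6 fell and 0 rose (7 fell when adjusted over the list alone). CNN1, calponin (-1.68 ± 0.261), and SYNPO2, an actin-binding protein (-1.44 ± 0.135), were furthest down. The median was -1.05 (adjusted p = 3.04e-09, and adjusted p = 0.0482 with an estimated correlation), and -1.11 with the actin 3' to 5' difference as a covariate. It was -0.658 with the mean of each gene's probe sets. Of 24 actin and contractility genes, 5 fell and 0 rose (8 fell when adjusted over the list alone), with ACTA2 at -1.39 ± 0.167. The median was -0.188 (adjusted p = 3.96e-05, and adjusted p = 0.199 with an estimated correlation), and -0.132 with the covariate. It was -0.0891 without BJ diploid array 2, -0.12 after cyclic loess and -0.125 with the mean of each gene's probe sets, which gave -0.658 for ACTA2.

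The lists of DNA replication genes and interferon-stimulated genes had negative medians in BJ cells, with calls for a minority of their members. Of 26 replication genes, 5 fell and 0 rose (15 fell when adjusted over the list alone). The helicase subunit genes MCM6 (-0.45 ± 0.0906) and MCM2 (-0.45 ± 0.0905) lost their calls without BJ diploid array 1 or BJ tetraploid array 1 (changes of -0.423 to -0.355, adjusted p up to 0.155). The replication median was -0.251 (adjusted p = 3.29e-09, and adjusted p = 0.159 with an estimated correlation), and -0.222 with the 3' to 5' covariate. Of 23 interferon-stimulated genes, 8 fell and 0 rose (10 fell when adjusted over the list alone), led by IFI27. MX1, an antiviral GTPase gene, fell by 1.12 ± 0.256 and lost its call without BJ diploid array 1 or 2 or BJ tetraploid array 1 (changes of -1.20 to -1.09, adjusted p up to 0.143). The interferon median was -0.303 (adjusted p = 3.29e-09, and adjusted p = 0.161 with an estimated correlation), and -0.287 with the covariate. Of 21 genes of the endoplasmic reticulum stress and amino acid response, 7 fell (9 adjusted over the list alone). The median was -0.235 (adjusted p = 1.21e-06, and adjusted p = 0.21 with an estimated correlation), and -0.252 with the covariate.

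More matrix genes fell than rose in BJ cells, and some fibroblast markers and distal HOX genes fell. Of 29 extracellular matrix genes, 5 fell and 2 rose (8 and 4 adjusted over the list alone). The matricellular protein genes THBS2 (-1.18 ± 0.126) and TNC (-1.16 ± 0.167) fell. The rises, of COL11A1 and THBS1 (0.615), lost their calls without BJ tetraploid array 1, 2 or 3. THBS1 had 0.356 without BJ diploid array 1, and 0.259 (adjusted p = 0.47) without probe sets that can match related transcripts. The median was -0.11 (adjusted p = 0.0261; 0.543 without BJ diploid array 2 and 0.0726 without BJ tetraploid array 1, and adjusted p = 0.531 with an estimated correlation), and -0.102 with the 3' to 5' covariate. The matrix median was -0.056 without BJ diploid array 2 and -0.179 without BJ diploid array 1, and the TNC change was -0.668 with the mean of its probe sets. The matrix call was also lost by fry (0.138), after quantile normalization (0.0773) and cyclic loess (-0.0291, 0.442), without dim genes (0.382), with the mean of each gene's probe sets (0.135) and without genes of chromosome 12 (-0.0717, 0.152). Of 18 fibroblast markers, 2 fell (5 fell and 1 rose when adjusted over the list alone), SFRP1 and the proteoglycan gene DCN (-0.75 ± 0.127). DCN read -0.42 with the mean of its probe sets and 0.0616 without probe sets that can match related transcripts. The fibroblast median was -0.157 (adjusted p = 0.0012, and adjusted p = 0.159 with an estimated correlation), -0.229 with the 3' to 5' covariate, and -0.396 without BJ diploid array 1. Of 10 distal HOX genes, 3 fell (4 fell and 1 rose when adjusted over the list alone), among them HOXD10 (-1.09 ± 0.145). The median was -0.0872 (adjusted p = 0.029; 0.06, 0.0519 and 0.0592 without BJ diploid array 1, BJ tetraploid array 2 and BJ tetraploid array 3, and adjusted p = 0.199 with an estimated correlation), and -0.089 with the covariate. The HOX median was -0.0571 without BJ tetraploid array 3 and -0.052 with the mean of each gene's probe sets.

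Several lists shifted in BJ cells by less than 0.13 at the median. Of 26 Hippo pathway components 2 fell (7 adjusted over the list alone). The median was -0.127 (adjusted p = 0.0076; 0.0576 without BJ tetraploid array 1, and adjusted p = 0.504 with an estimated correlation), and -0.0997 with the 3' to 5' covariate. Of 21 YAP and TEAD targets 1 fell, TGFB2 (-1.12 ± 0.0987; 2 adjusted over the list alone). The median was -0.127 (adjusted p = 0.0353; 0.416 without BJ diploid array 1 and 0.098 without BJ tetraploid array 1, and adjusted p = 0.531 with an estimated correlation; 0.321 with the 3' to 5' covariate). Of 24 oxidative phosphorylation genes 1 fell (1 adjusted over the list alone). The median was -0.121 (adjusted p = 0.000603, and adjusted p = 0.46 with an estimated correlation), and -0.0528 with the covariate. Of 20 hypoxia and glycolysis genes 2 fell (4 adjusted over the list alone). The median was -0.0855 (adjusted p = 0.00946; 0.147 without BJ diploid array 2, and adjusted p = 0.273 with an estimated correlation), and -0.126 with the covariate. Of 19 centriole and centrosome genes 1 fell (5 adjusted over the list alone). The median was -0.0711 (adjusted p = 0.0203; 0.521 without BJ diploid array 1 and 0.0555 without BJ tetraploid array 1, and adjusted p = 0.517 with an estimated correlation; 0.151 with the covariate). Of 21 ribosomal protein genes 1 fell (1 adjusted over the list alone). The median was -0.0791 (adjusted p = 0.0076, and adjusted p = 0.397 with an estimated correlation), -0.0798 with the covariate, and 0.0038 after cyclic loess scaling. Of 14 cholesterol synthesis genes none passed (1 rose when adjusted over the list alone). The median was 0.0986 (adjusted p = 0.0246; 0.274 without BJ diploid array 2 and 0.142 without BJ tetraploid array 2, and adjusted p = 0.397 with an estimated correlation), and 0.181 with the covariate. After quantile normalization and cyclic loess, adjusted p was 0.0616 and 0.0743 for the Hippo list, 0.222 and 0.502 for YAP and TEAD targets, 0.056 and 0.201 for oxidative phosphorylation, 0.056 and 0.0993 for hypoxia, 0.0707 and 0.0743 for centrosome genes, and 0.0616 and 0.909 for ribosomal genes. The medians after these scalings were -0.0659 and -0.0751 for YAP and TEAD targets, -0.055 and -0.0659 for oxidative phosphorylation and -0.0297 and -0.0466 for hypoxia, and after quantile normalization -0.0539 for the Hippo list and 0.16 for cholesterol genes. The calls of the Hippo list (-0.0537, adjusted p = 0.0827), YAP and TEAD targets (-0.0855, 0.124) and centrosome genes (-0.0413, 0.0971) were lost with the mean of each gene's probe sets. That setting gave -0.0475 for hypoxia, -0.0483 for oxidative phosphorylation and -0.0392 for ribosomal genes, all still past the threshold. By fry adjusted p was 0.138 for the Hippo, YAP and TEAD target, centrosome and cholesterol lists. The centrosome median was -0.255 without BJ diploid array 2, -0.113 without BJ tetraploid array 3, -0.0502 without BJ diploid array 1 and -0.121 without genes of chromosome 12, and the hypoxia median -0.174 and -0.0525 without BJ diploid arrays 1 and 2. The Hippo median was -0.0803 without BJ tetraploid array 1, and that of YAP and TEAD targets -0.0565 without BJ diploid array 1. Cholesterol genes had 0.0528 and 0.056 without BJ diploid array 2 and BJ tetraploid array 2. Without dim genes adjusted p was 0.0545, 0.303, 0.146 and 0.0545 for the Hippo, YAP and TEAD target, centrosome and ribosomal lists.

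The remaining 13 lists did not pass in BJ cells, with adjusted p from 0.0583 to 0.852. Of 27 p53 targets 0 passed, at a median of -0.0581. Of 30 mitosis genes 3 fell and 1 rose. The rise, of ANLN (0.577), was lost with the 3' to 5' covariate (0.382, adjusted p = 0.0907) and without BJ tetraploid array 1 or 2. TOP2A (-0.625) lost its call without BJ tetraploid array 1, 2 or 3 and had -0.273 without BJ diploid array 1. CDK1 (-0.543) lost its call without BJ tetraploid array 1 or 3. Of 22 inflammatory factors and proteases 2 rose and 1 fell. The stromelysin gene MMP3 (0.94 ± 0.156) and MMP1 (0.55 ± 0.0984) rose and CCL2 (-1.60 ± 0.245) fell. The MMP3 change was 0.573 without BJ diploid array 1. The MMP1 call was lost without BJ diploid array 1 (0.493, adjusted p = 0.0787). Of 20 G1 cyclins, kinases and inhibitors 1 rose, CCND1, and 1 fell. By camera 0 of 23 chromosomes passed in BJ cells (smallest adjusted p = 0.0716, and adjusted p = 0.167 with an estimated correlation), 2 had an unadjusted p under 0.05, and 1 passed by fry. In the windows of 40 brighter genes, the first 4 of 13 windows of chromosome 7, 160 such genes from FAM20C to PPIA, were higher. The other 13 windows past the level were lower, on 9 chromosomes. The median of the 160 genes on chromosome 7 exceeded that of other brighter genes by 0.202. Of the 160, 83.8% had positive changes, and 23 were called higher and 0 lower. These genes were picked for being high in this comparison, so the values describe the region and are no separate test. The same genes differed by 0.0119 in RPE cells.

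**Figure D3:**
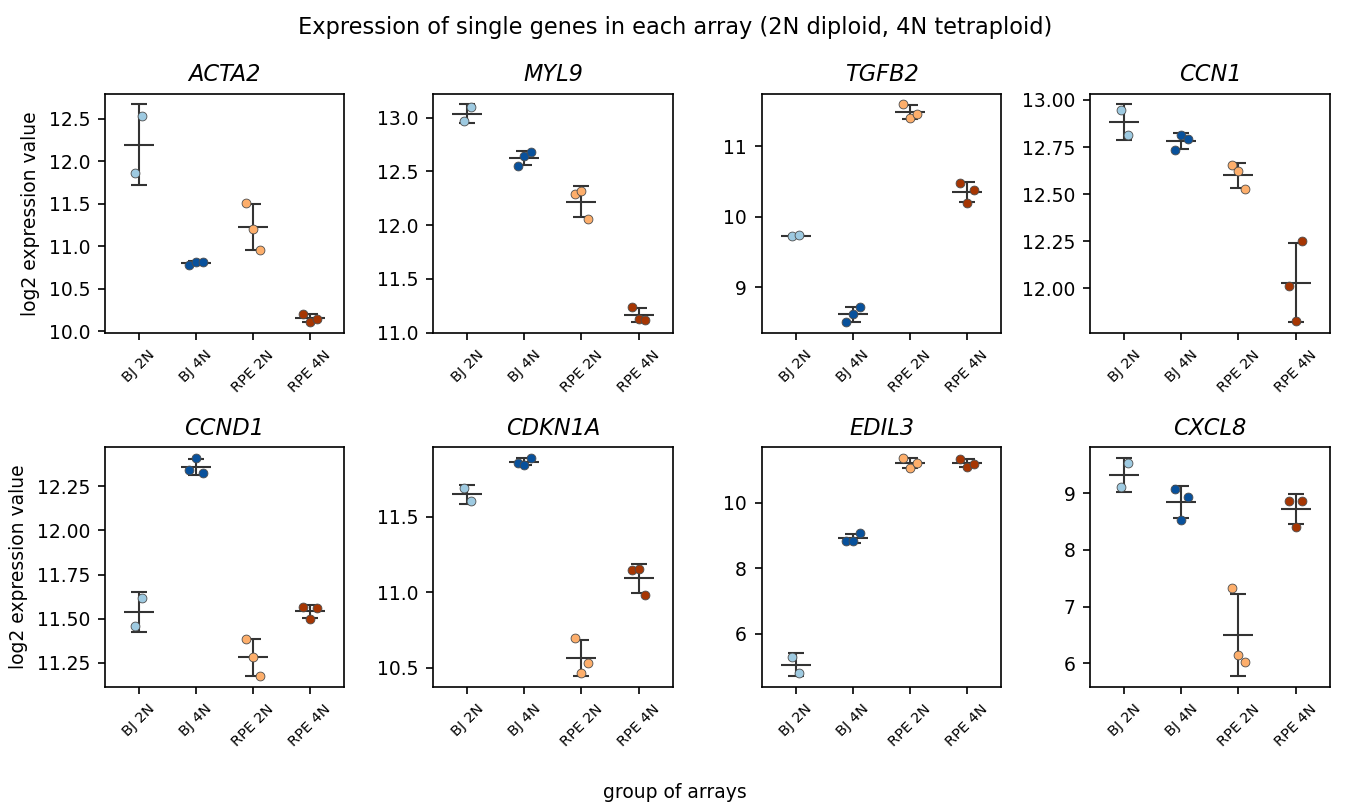
Log2 expression values (vertical axis) of 8 genes in each array (points) of 4 groups (horizontal axis; 2N diploid, 4N tetraploid), with the group mean and SD (n = 2 for BJ diploid, n = 3 otherwise). ACTA2 and TGFB2 were lower in tetraploid arrays of both lines, whereas CCND1 rose in BJ (0.82), CDKN1A in RPE (0.53), EDIL3 in BJ (3.88) and CXCL8 in RPE (2.21). The direct test of a difference between the lines did not pass for CDKN1A.

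The third question was which genes changed the same way in both lines. The chemokine gene CCL2 (-1.18 in RPE and -1.60 in BJ), TNS1, which links actin to focal adhesions (-1.30 and -1.13), TGFB2 (-1.13 and -1.12), ACTA2 (-1.07 and -1.39), SRGN (-1.07 and -1.92), LMOD1 (-1.53 and -1.05) and the interferon-induced GTPase gene GBP1 (-1.04 and -1.23) fell in both. Without probe sets that can match related transcripts TNS1 had -0.728 in BJ, and with the mean of its probe sets -0.68 and -0.592. SULF1 also fell in both (-1.62 and -1.09), but its BJ call was lost without BJ diploid array 1 or 2 or BJ tetraploid array 1 or 2 (changes of -1.25 to -0.935, adjusted p up to 0.118). In all, 112 genes fell in both lines, against 20.6 expected from independent lists (Fisher's exact test p = 6.08e-51, and genes are not independent). The expected counts took all genes, dim ones included, as equally likely to be called. The contrasts of the lines also shared each gene's variance estimate. These points can raise every overlap, and opposite calls, given below, exceeded their expected counts too. The excess is therefore no measure of shared regulation alone. Only 10 genes rose in both, against 3.79 expected (p = 0.00494 by the same exact test), among them NTM (0.93 and 0.58; 0.312 in BJ with the mean of its probe sets), the hyaluronan receptor gene CD44 (0.45 in each; 0.34 in BJ without BJ diploid array 2, adjusted p = 0.0614) and ID1 (0.47 and 0.42, and adjusted p = 0.0614 in BJ without BJ diploid array 1). Other named rises depended on the setting. LPXN (0.703 in RPE and 0.699 in BJ) had 0.0737 and 0.0802 without probe sets that can match related transcripts. In that setting ADGRL2 (0.618 and 0.871) had -0.177 and -0.103. With the mean of probe sets SEMA3A had 0.332 in BJ (adjusted p = 0.0879) and JAM2 0.247 (0.119). PHLDA1 (0.518 in BJ, and 0.228 without BJ diploid array 2) lost its BJ call without BJ tetraploid array 1, 2 or 3. Opposite calls numbered 31 for higher in RPE and lower in BJ (13.2 expected, exact p = 1.18e-05) and 12 for the reverse (5.93 expected, exact p = 0.0186). The 31 were 18 without BJ diploid array 1 and 16, 19 and 20 without BJ tetraploid arrays 1, 2 and 3, and the 12 were 7 and 21 without BJ diploid arrays 1 and 2. Across all genes the changes in the lines correlated weakly (Pearson r = 0.153, Spearman rho = 0.154; genes are not independent replicates). The count of 122 genes changed the same way was 75 without BJ diploid array 1, 67 without BJ tetraploid array 1 and 71 without BJ tetraploid array 2, with 67, 61 and 66 of them lower, and r was 0.0727 without RPE diploid array 1. The 10 higher genes were 17 without BJ diploid array 2, 6 and 5 without BJ tetraploid arrays 1 and 2, and 17 after quantile normalization.

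A direct test of the difference between the lines, the RPE change less the BJ change, called 708 genes, 475 positive and 233 negative. The largest positive differences were of PTX3 (3.27 ± 0.26), CXCL8 (2.68 ± 0.411), TCIM (2.59 ± 0.284) and the laminin gene LAMA4 (2.58 ± 0.225; 0.164 without probe sets that can match related transcripts), all at an adjusted p of at most 0.00243. EGR1, an immediate early transcription factor, differed by 2.91 ± 0.739 (adjusted p = 0.0466) with an SD of 1.52 among tetraploid RPE arrays. The call was lost without any 1 of the 5 BJ arrays or of the 3 diploid RPE arrays (changes of 2.76 to 3.04, adjusted p up to 0.161). The largest negative differences were of EDIL3 (-3.88 ± 0.188), MGARP (-2.07 ± 0.239), GFRA1 (-1.98 ± 0.138), the phosphodiesterase gene PDE1C (-1.73 ± 0.127) and IGFBP5 (-1.72 ± 0.139). With the mean of each gene's probe sets these were smaller for EDIL3 (-1.71), GFRA1 (-1.31), IGFBP5 (-0.741) and LAMA4 (0.691). TCIM, EDIL3 and MGARP each had a group under the median of every array, so the sizes and order of their differences are uncertain. Among 28 lists, the difference was positive for 11 and negative for 3 by camera, whichever line had changed, and 0 of the 14 passed with an estimated correlation (smallest adjusted p = 0.212). Stress response genes (median difference 0.326, 4 of 21 positive, 9 adjusted over the list alone) and interferon-stimulated genes (0.282, 6 of 23 positive, 10 adjusted over the list alone) were among those with a positive difference. The interferon list did not pass in RPE (median 0.0313, adjusted p = 0.827 by camera). YAP and TEAD targets (-0.116, 2 of 21 negative, 5 adjusted over the list alone) had a negative difference, of -0.204 without BJ diploid array 1, -0.202 without RPE diploid array 2, -0.185 without RPE tetraploid array 1 and -0.257 with the covariate, and adjusted p was 0.0787 by fry. For chromosome 12 genes the median difference exceeded that of other genes by 0.11 (adjusted p = 4.21e-09, and adjusted p = 0.00179 with an estimated correlation). Of the genes fixed in advance, CCND1 differed (-0.56 ± 0.112, adjusted p = 0.0131; -0.482 and 0.073 without BJ diploid array 1), whereas the difference of CDKN1A (0.31 ± 0.118, adjusted p = 0.198) and that of CCN1 (-0.47, adjusted p = 0.103) did not pass. The count of 708 was 424 (277 positive and 147 negative) without BJ diploid array 1 and 470 with the 3' to 5' covariate. The positive differences numbered 305 without BJ tetraploid array 1 and 302 without RPE diploid array 3, and the negative ones 151 without BJ tetraploid array 2.

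Diploid cells of the lines differed in fibroblast markers, whereas the list of retinal pigment epithelium markers did not pass. Against BJ, RPE cells were higher in MEST (6.65 ± 0.0857, n = 3 against 2), the Notch-related gene DNER (6.20), EDIL3 (6.17), RGS4 (5.55) and PNMA2 (5.55). BJ cells were higher in the collagenase gene MMP1 (-8.72 ± 0.0984), the collagen genes COL3A1 (-8.65) and COL1A2 (-8.19), the proteoglycan gene LUM (-8.42) and the chemokine gene CXCL12 (-7.47). In 7 of these 10 genes, all but MEST, RGS4 and COL1A2, the lower line lay under the median of every array. MMP1 and LUM had means of 3.70 in RPE, where the lowest value of any gene was 3.14. Signal over background is unknown there and in other genes as dim, so these differences give the direction but not the size or the order. Without probe sets that can match related transcripts COL3A1 had -1.65, LUM -2.38 and COL1A2 -3.17. COL3A1 had -5.33, LUM -5.4 and EDIL3 3.78 with the mean of each gene's probe sets. Of 18 fibroblast markers, 17 were lower and 1 was higher in RPE (the same adjusted over the list alone), the exception being SFRP1 (4.21 ± 0.0742). The median was -3.18 (adjusted p = 2.15e-20, and adjusted p = 0.00207 with an estimated correlation). Of 29 matrix genes 22 were lower and 3 higher (median -2.42, -1.45 with the mean of each gene's probe sets, and adjusted p = 0.0356 with an estimated correlation), and of 10 distal HOX genes 6 were lower, among them HOXC10 (-2.44) and HOXD10 (-2.26; -1.35 with the mean of its probe sets), and adjusted p of the list was 0.0358 with an estimated correlation. Of 16 retinal pigment epithelium markers 3 were higher and 0 lower, with OTX2 (3.38) and PAX6 (2.99), transcription factors of the eye (adjusted p of the list 0.145, and adjusted p = 0.483 with an estimated correlation). Of 15 epithelial markers 3 were higher and 4 lower. The keratin gene KRT8 was higher in RPE (3.87), and KRT19 was higher in BJ (-3.07; -1.53 with the mean of its probe sets). Of 30 mitosis genes 28 and of 26 replication genes 22 were higher in RPE (medians 0.763 and 0.543, and adjusted p = 0.0222 and 0.0358 with an estimated correlation). In all, 4930 genes differed, 2554 higher and 2376 lower in RPE, and 964 of them at least 2-fold.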

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

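The tests for more copies of chromosome 12 and for slower cycling were chosen after the results were seen.

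The RPE change less the BJ change passed the threshold for PTX3 (3.27), EGR1 (2.91), CXCL8 (2.68), TCIM (2.59) and LAMA4 (2.58), and in the other direction for EDIL3 (-3.88), MGARP (-2.07), GFRA1 (-1.98), PDE1C (-1.73) and IGFBP5 (-1.72). In TCIM, EDIL3 and MGARP a group lay under the median of every array, so these sizes are uncertain. The EGR1 call was lost without any 1 of the 5 BJ arrays or 3 diploid RPE arrays (adjusted p up to 0.161). The difference also passed for 14 gene lists by camera with the preset correlation, and for none of them with an estimated correlation (smallest adjusted p = 0.212); 16 had an unadjusted p under 0.05 by camera and 12 passed by fry. Its median was positive for stress response genes (0.326), fibroblast markers (0.286), interferon-stimulated genes (0.282), DNA replication genes (0.263), inflammatory factors (0.237), centrosome genes (0.214), mitosis genes (0.203), p53 targets (0.198), ribosomal protein genes (0.124), oxidative phosphorylation genes (0.116) and smooth muscle markers (0.102). It was negative for cholesterol synthesis genes (-0.223), actin genes (-0.139) and YAP and TEAD targets (-0.116). Without BJ diploid array 1 the adjusted p was 0.0579 for centrosome genes and 0.0761 for actin genes, and the median was 0.284 for smooth muscle markers and -0.204 for YAP and TEAD targets. Without BJ diploid array 2 the median was 0.109 for inflammatory factors (adjusted p = 0.162), 0.145 for fibroblast markers (0.063), 0.069 for smooth muscle markers (0.26) and 0.355 for centrosome genes. The smooth muscle median was 0.178, 0.158 and 0.155 without BJ tetraploid array 2, RPE diploid array 2 and RPE tetraploid array 2, and that of YAP and TEAD targets -0.202 and -0.185 without RPE diploid array 2 and RPE tetraploid array 1. The adjusted p was 0.0513 for fibroblast markers without RPE diploid array 1, and for smooth muscle markers 0.0953 without RPE diploid array 3 and 0.0513 without RPE tetraploid array 3. Oxidative phosphorylation genes lost the call after cyclic loess (0.0583, adjusted p = 0.0644), with the 3' to 5' covariate (0.0674, adjusted p = 0.0583) and by fry (0.0653), and ribosomal protein genes after cyclic loess (0.0587, adjusted p = 0.196). Smooth muscle markers lost it without dim genes (0.197, adjusted p = 0.103), after quantile normalization (0.0541) and after cyclic loess (0.0701). Actin genes lost it with the mean of probe sets (-0.0519, 0.21) and by fry (0.0778), centrosome genes by fry (0.0778), YAP and TEAD targets by fry (0.0787), and fibroblast markers without both RPE arrays numbered 1 (0.107). With the mean of probe sets the median was 0.119 for centrosome genes, 0.0535 for oxidative phosphorylation and 0.018 for smooth muscle markers. With the covariate it was -0.257 for YAP and TEAD targets, 0.115 for p53 targets, 0.0963 for centrosome genes and -0.0583 for actin genes, and without dim genes it was 0.425 for inflammatory factors. Genes on chromosome 12 differed between the lines by 0.11. Among 11721 probe sets with no gene name, which the comparisons did not use, 85 passed in RPE and 47 in BJ.

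Chromosome 12 genes were higher in tetraploid RPE arrays. The median excess was at least 0.0957 under 3 other normalizations. These rescale whole arrays and could hardly move genes of 1 chromosome against equally bright genes. The excess was 0.1 with the 3' to 5' covariate, but mean actin differences were close in diploid and tetraploid RPE arrays (0.285 and 0.315). Neither setting could decide its question. Relative to the diploid mean, the excess in brighter genes was 0.199, 0.187 and 0.184 in tetraploid arrays 1, 2 and 3. Their actin differences were 0.556, 0.228 and 0.16. It was -0.00436, 0.00147 and 0.00176 in diploid arrays 1, 2 and 3, with actin differences of 0.46, 0.142 and 0.255. The excess did not follow the actin difference, which argues against RNA quality, as read by actin, as its cause. Brightness as the cause is argued against by 0% of 10000 brightness-matched random gene sets reaching the median of chromosome 12 genes. The highest of these sets had 0.0163, against 0.102 for chromosome 12. The same values argue against a normalization that acts by brightness alone. More copies of chromosome 12 in the tetraploid cells is a candidate explanation. In this comparison 100% of its windows were above the 95th percentile of windows elsewhere (lowest 0.0908, against 0.0424), which restates the pattern and is no separate support. A step from 4 to 5 copies is a log2 ratio of 0.322. The median excess was smaller, 0.0994 over all genes of the chromosome and 0.192 in the brighter ones. How far array values follow copies was not tested. No measurement of DNA copies was analysed here, so the hypothesis stays open. The 10 splits of the 6 RPE arrays are too few for a share under 0.05 (real excess 0.0994, highest other 0.0538).

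More genes were lower than higher in tetraploid BJ arrays. With the 3' to 5' covariate 73.2% of 310 called genes were lower, and the covariate lowered the count of called genes from 788. The actin difference did not overlap between the BJ groups, so the covariate's slope came mostly from the spread among RPE arrays. It could not separate RNA quality from ploidy in BJ, and RNA quality stays open. Without either diploid array at least 71.4% were lower, which argues against a single diploid array. The share was 78.2% after cyclic loess and 85.4% after median centring, against 77.7% as analysed, and 69.7% after quantile normalization. The last value was just under the bound of 70% set for this test. These settings all bring the arrays to like levels, as the deposited values already were. They could not test a shift of most genes one way, so normalization stays open. Higher and lower are relative to the other genes of an array. No biological explanation was tested.

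The list of actin and contractility genes had negative medians in tetraploid arrays of both lines, -0.344 in RPE and -0.188 in BJ, and did not pass with an estimated correlation (adjusted p = 0.0861 and 0.199). Of its 24 members, 12 were called lower in RPE, 5 in BJ and 4 in both. Without BJ diploid array 2 the BJ median was -0.0891. RNA quality stays open as part of the cause: with the 3' to 5' covariate the medians were -0.343 in RPE and -0.132 in BJ, and the latter lay between the bounds set for the test. In RPE the mitosis list was higher, which goes against slower cycling as the cause (median 0.133, adjusted p = 6.34e-06, 0.0107 by fry and 7.51e-05 without genes of chromosome 12). It was not past the threshold with an estimated correlation (0.237). Of its members 4 were called higher, 2 of them on chromosome 12. The replication list did not pass in RPE, with 0 members called higher, and the kinase inhibitor gene CDKN1A rose. Levels of these lists do not measure the rate of cycling, so slower cycling was not excluded. In BJ slower cycling stays open: the mitosis median was -0.0342 (adjusted p = 0.26), and the DNA replication list had a median of -0.251 (adjusted p = 3.29e-09, and adjusted p = 0.159 with an estimated correlation) with 5 of 26 members called lower. A change in cell tension or shape with ploidy was not tested.

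For the number of genes called in RPE, the 10 splits of 6 arrays are too few for a share under 0.05 (real value 1092, highest other 0), and the same holds for the number of lists (11, highest other 9). Mixed splits that called 0 genes still called 1 to 9 lists, so lists can pass at the preset correlation without any called gene. The correlation of changes between the lines was reached in 21 of 100 pairs of splits, the real pair among them (0.1534, highest other 0.2828). Some pairs hold the real split of 1 line, and mixed splits keep part of the ploidy change. They are no clean reference, and chance was not excluded for the correlation.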

How the results depend on the processing

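The 3' to 5' covariate, leaving out both RPE arrays numbered 1 and leaving out chromosome 12 were chosen after the data were seen. Of 7377 alternatives of named genes, 6557 kept direction and side of the threshold, 792 lost the call, 18 gained one and 10 reversed; of 1186 of lists, 1061 kept both, 124 lost the call and 1 reversed; of 84 of chromosomes, 83 kept both and 1 lost the call. A reversal was a change of sign in a lost call, and none passed the threshold (adjusted p of 0.341 to 0.999 for genes and 0.909 for the list). The cause of a change was not tested unless the setting tested fewer genes or arrays.

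Without _x_at and _s_at probe sets, calls numbered 699 in RPE, 520 in BJ, 456 for the difference and 81 shared. With an absolute change of at least 1 they numbered 79, 73, 144 and 9, and 964 between the diploid cells, for which every probe set gave 9298. With only the groups compared, BJ had 339 and the shared count was 60; trend and robust variances gave 190 shared. With the covariate, BJ had 310, the difference 470 and the shared count 61, and r was 0.108. Without both RPE arrays numbered 1 the counts were 590 in RPE, 471 for the difference and 76 shared, and r was 0.105. With a replicate block, calls numbered 1057 in RPE, 593 in BJ, 618 for the difference, 86 shared and 4775 between diploid cells. The array numbers were not used as a pairing. In RPE, each diploid array's deviations from group means correlated most with the same-numbered tetraploid array (r = 0.259, 0.154 and 0.0607). With other numbers r was at most -0.115, 0.0651 and 0.0105. In BJ the same numbers gave -0.114 and -0.0323, against up to 0.0839 and 0.114. The block gave each number a single effect across both lines, so it did not test a pairing within RPE.

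With an estimated correlation 0 lists passed in RPE, 1 in BJ and 0 for the difference. BJ had 9 lists without dim genes, 8 after quantile normalization and 8 after cyclic loess. In BJ, 1 chromosome passed by fry, 2 with the mean of probe sets and 2 without dim genes.

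Leaving out 1 array gave 688 (without RPE tetraploid array 2) to 1194 genes in RPE, 340 (without BJ tetraploid array 1) to 1069 in BJ (344, 400 and 499 without BJ diploid array 1 and BJ tetraploid arrays 2 and 3), 424 (without BJ diploid array 1) to 942 for the difference, 67 (without BJ tetraploid array 1) to 118 shared (75 and 71 without BJ diploid array 1 and BJ tetraploid array 2), 3943 to 4914 between diploid cells, and r of 0.0727 (without RPE diploid array 1) to 0.208. It gave 10 to 12 lists in RPE, 11 to 16 in BJ and 12 to 15 for the difference, 2 chromosomes in RPE and 0 in BJ. A lone BJ diploid array was assumed to vary like the other groups.

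The ribosomal list in BJ reversed after cyclic loess (0.0038). Without _x_at and _s_at probe sets, reversals were of ADGRL2 (-0.177 in RPE, -0.103 in BJ), EMCN in RPE (-0.0684), CDK5RAP2 (0.0964), CA12 (0.112) and DCN (0.0616) in BJ, FAS (-0.0651), MYL9 (0.00121) and DCN (-0.065) for the difference, and RPS6 between diploid cells (-0.136). Signal over background could not be computed from these values, so dim genes were only left out by brightness.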

Other observations

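The windows of 40 neighbouring genes and the test of RPE cells among BJ cells were chosen after results were seen.

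Genes at the start of chromosome 7 were higher in tetraploid BJ arrays, with a median excess of 0.202 in 160 brighter genes. The excess was 0.197 with the 3' to 5' covariate, which could not separate RNA quality from ploidy in BJ, so RNA quality stays open. A single array as the cause is argued against by the 6 pairs of a tetraploid and a diploid array, whose excess lay between 0.207 and 0.226. The region was picked because its windows were past the level in this same comparison, so the size of the excess is no separate support. A gain of this region in the tetraploid BJ cells is a hypothesis that was not tested.

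EDIL3 rose in tetraploid BJ arrays from a mean of 5.05 to 8.92, towards the mean of 11.2 in diploid RPE arrays. RPE cells among the BJ tetraploid cells as a source is argued against, since the other 4 genes named as highest in RPE had a median change in BJ of -0.329 (MEST -0.42, DNER -0.17, RGS4 -1.22 and PNMA2 -0.23). A mixture with 19.2% RPE cells, enough for the EDIL3 rise, would have raised them by 3.29 to 4.33.

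On chromosome 10, diploid RPE arrays exceeded diploid BJ arrays by 0.0737 at the median (adjusted p = 0.00146; adjusted p = 0.0504 with an estimated correlation), with 6 of 11 windows above the level of 0.194 that shuffled gene orders set.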
